A study of Rattus norvegicus with 12 samples.

How the data were processed

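The data were 12 RNA sequencing libraries of cultured rat cardiomyocytes. The labels give a design with a control or a Wnt5a siRNA, with or without cell stretch, and 3 numbered libraries per group. Per the labels' protocols, total RNA was extracted with miRNeasy and libraries were made with a TruSeq stranded mRNA kit, which selects polyadenylated RNA and keeps the strand. Per the submitters' processing notes, the tools were TopHat2 2.1.1, Bowtie2 and Cuffdiff 2.2.1 with the rat genome build rn6. The deposited values are the authors' FPKM from these tools, counts of fragments per gene symbol divided by transcript length and library size. The gene annotation, the normalization between libraries, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Genes that overlap, antisense partners and near-identical copies, such as ribosomal protein genes with their pseudogenes, are therefore uncertain. Genes shorter than the fragments, such as Mir6326 and Rmrp, have unstable FPKM, and a value of 0 can be a failed estimate.

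Each library held the same 17312 symbols. Against a table of rat gene names for the assembly GRCr8, 14809 symbols were current and 2117 were synonyms. The table was used for names only, because its assembly is not the one of the data, and no coordinates are given.

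The depth is unknown, since FPKM hold no counts. The value of 1 fragment was estimated from 2284 genes whose FPKM stayed under 0.5. Of 1523 of these above 0 in at least 3 libraries, 1457 (95.7%) had values in whole-number ratios, to within 0.03. The value of 1 fragment spanned a factor of 1.21, which includes scaling between libraries. Fragments were not recovered and no count test was run. Precision is given by the spread between libraries alone, with 8 residual degrees of freedom.

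Values were transformed to log2(FPKM + 1), and the 10518 genes with FPKM of at least 1 in at least 3 libraries were tested. The log2 changes are on this scale, which understates the change of low genes. A model of the 4 group means was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), which gives all comparisons a common estimate of the spread. The tests were 2-sided, and p-values were adjusted over the genes of each comparison by Benjamini and Hochberg, with 0.05 as the threshold. The 5 comparisons were stretch with control siRNA, Wnt5a siRNA with stretch, Wnt5a siRNA without stretch, stretch with Wnt5a siRNA, and the interaction of both.

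From knowledge of cardiac and Wnt biology, 34 gene lists with 873 members were written, 812 of which the data list. The 32 lists with at least 5 tested members were tested against the other genes with camera from limma, with its preset correlation of 0.01, and adjusted over the lists. An estimated correlation between genes and fry were run as alternatives. Overlaps between comparisons that share libraries were set beside values from 100 simulations in which unchanged groups were compared with those libraries.

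The genes named follow a rule. They are Wnt5a and 8 readouts (Cyr61, Ctgf, Ankrd1, Nppa, Nppb, Acta1, Myh7 and Yap1), then the called genes with the largest changes and then members of the lists. The largest changes were taken from genes with an adjusted p under 0.05, a mean of at least 5 FPKM in the higher group and no overlap between the libraries of the groups. The overlap was not asked of the interaction, and provisional symbols made of LOC or RGD and digits were passed over. Up to 8 rises and 8 falls were taken for stretch with control siRNA and for Wnt5a siRNA under stretch, and up to 5 of each elsewhere. From each list came up to 4 called members with the smallest adjusted p, or up to 2 of the most abundant where none was called. The text names fewer than this, in the same order, and some genes that the rule takes are not reported here.

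The alternatives were a pseudocount of 0.1, no filter on low values, a filter at FPKM 5, median ratio scaling, quantile normalization, the replicate number as a block, eBayes without a trend, only the libraries of the groups compared, calls of at least 1.5-fold, and leaving out each library. The deviations from the group means of unstretched and stretched Wnt5a siRNA libraries with the same number correlated at 0.143 to 0.242 over the 3 pairs, so for stretch with Wnt5a siRNA a call that the block changes is given beside the result. TPM scaling was added after the data were seen. Median ratio factors were 1.0001 to 1.0061, so that scaling was already in the values. Summing repeated symbols was planned, but none was repeated.

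The fit was tested on simulated data with 100 of 10518 genes changed by 1.5-fold and 100 by 3-fold. For stretch with control siRNA 80% of the smaller and 100% of the larger changes were called, with 14 false calls among 194. For Wnt5a siRNA the shares were 77% and 100% with stretch and 83% and 100% without it, for stretch with Wnt5a siRNA 76% and 100%, and for the interaction 36% and 99%, with 9 false calls among 144. Camera called 10 of 10 simulated lists shifted by 0.4 log2 and 0 of 30 unshifted, but correlation between genes was not simulated. Principal components and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.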

Results

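The data were RNA sequencing of cultured rat cardiomyocytes, the contractile cells of the heart, which the series describes as taken from the ventricles of newborn animals. The 12 libraries formed 4 groups of 3. Cells received a control siRNA or an siRNA against Wnt5a, a secreted Wnt ligand, and were left unstretched or were stretched. The groups are called here unstretched control, stretched control, unstretched Wnt5a siRNA and stretched Wnt5a siRNA. Every library held FPKM for the same 17312 gene symbols, of which 13770 were above 0 in at least 1 library and 10518 passed the filter on low values. Summed FPKM ran from 588509 to 598628 in the unstretched control, 575161 to 607276 in the unstretched Wnt5a siRNA, 676014 to 709021 in the stretched control and 619742 to 659933 in the stretched Wnt5a siRNA libraries. FPKM do not give read numbers, and the value of 1 fragment, within a factor of 1.21, includes scaling between libraries. Levels are mean FPKM ± SD (n = 3), log2 changes are of log2(FPKM + 1) ± SE, and adjusted p-values of genes are from limma. The labels do not say that the numbered replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

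Wnt5a itself was at 12.3, 10.4 and 11.6 FPKM in the unstretched control libraries and at 6.15, 4.60 and 6.81 in the unstretched Wnt5a siRNA libraries. The siRNA mean was 51.2% of the control mean, a log2 change of −0.87 ± 0.14 (95% interval −1.17 to −0.56, adjusted p = 0.0014). In the stretched control libraries Wnt5a was at 6.52, 5.66 and 8.22 FPKM, 59.5% of the unstretched control (log2 change −0.68 ± 0.14, interval −0.99 to −0.38, adjusted p = 0.0014). The stretched Wnt5a siRNA libraries were at 6.22, 5.88 and 5.56 FPKM, 86.5% of the stretched control, and this difference did not pass the test (log2 change −0.17 ± 0.14, interval −0.47 to 0.14, adjusted p = 0.387). It was −0.28 without stretched control 2, −0.04 without stretched control 3, −0.29 after quantile normalization and −0.07 with TPM scaling. Under stretch the target transcript therefore gave no check of the siRNA labels. With Wnt5a siRNA the level under stretch was 100.6% of that without stretch (interval −0.28 to 0.32, adjusted p = 0.948). Exact 2-sided permutation p-values on log2(FPKM + 1) were 0.1 for stretch with control siRNA, 0.3 for Wnt5a siRNA under stretch, 0.1 for Wnt5a siRNA without stretch and 0.9 for stretch with Wnt5a siRNA. An exact test of 3 against 3 cannot go below 0.1. The change with stretch differed between the siRNAs by 0.70 ± 0.20 (adjusted p = 0.0244, 0.0048 to 0.0559 over the alternatives). That difference did not pass without stretched control 1 (0.0524), unstretched control 1 (0.0514) or 3 (0.0559), stretched Wnt5a siRNA 1 (0.0535) or unstretched Wnt5a siRNA 2 (0.055).

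**Figure D1:**
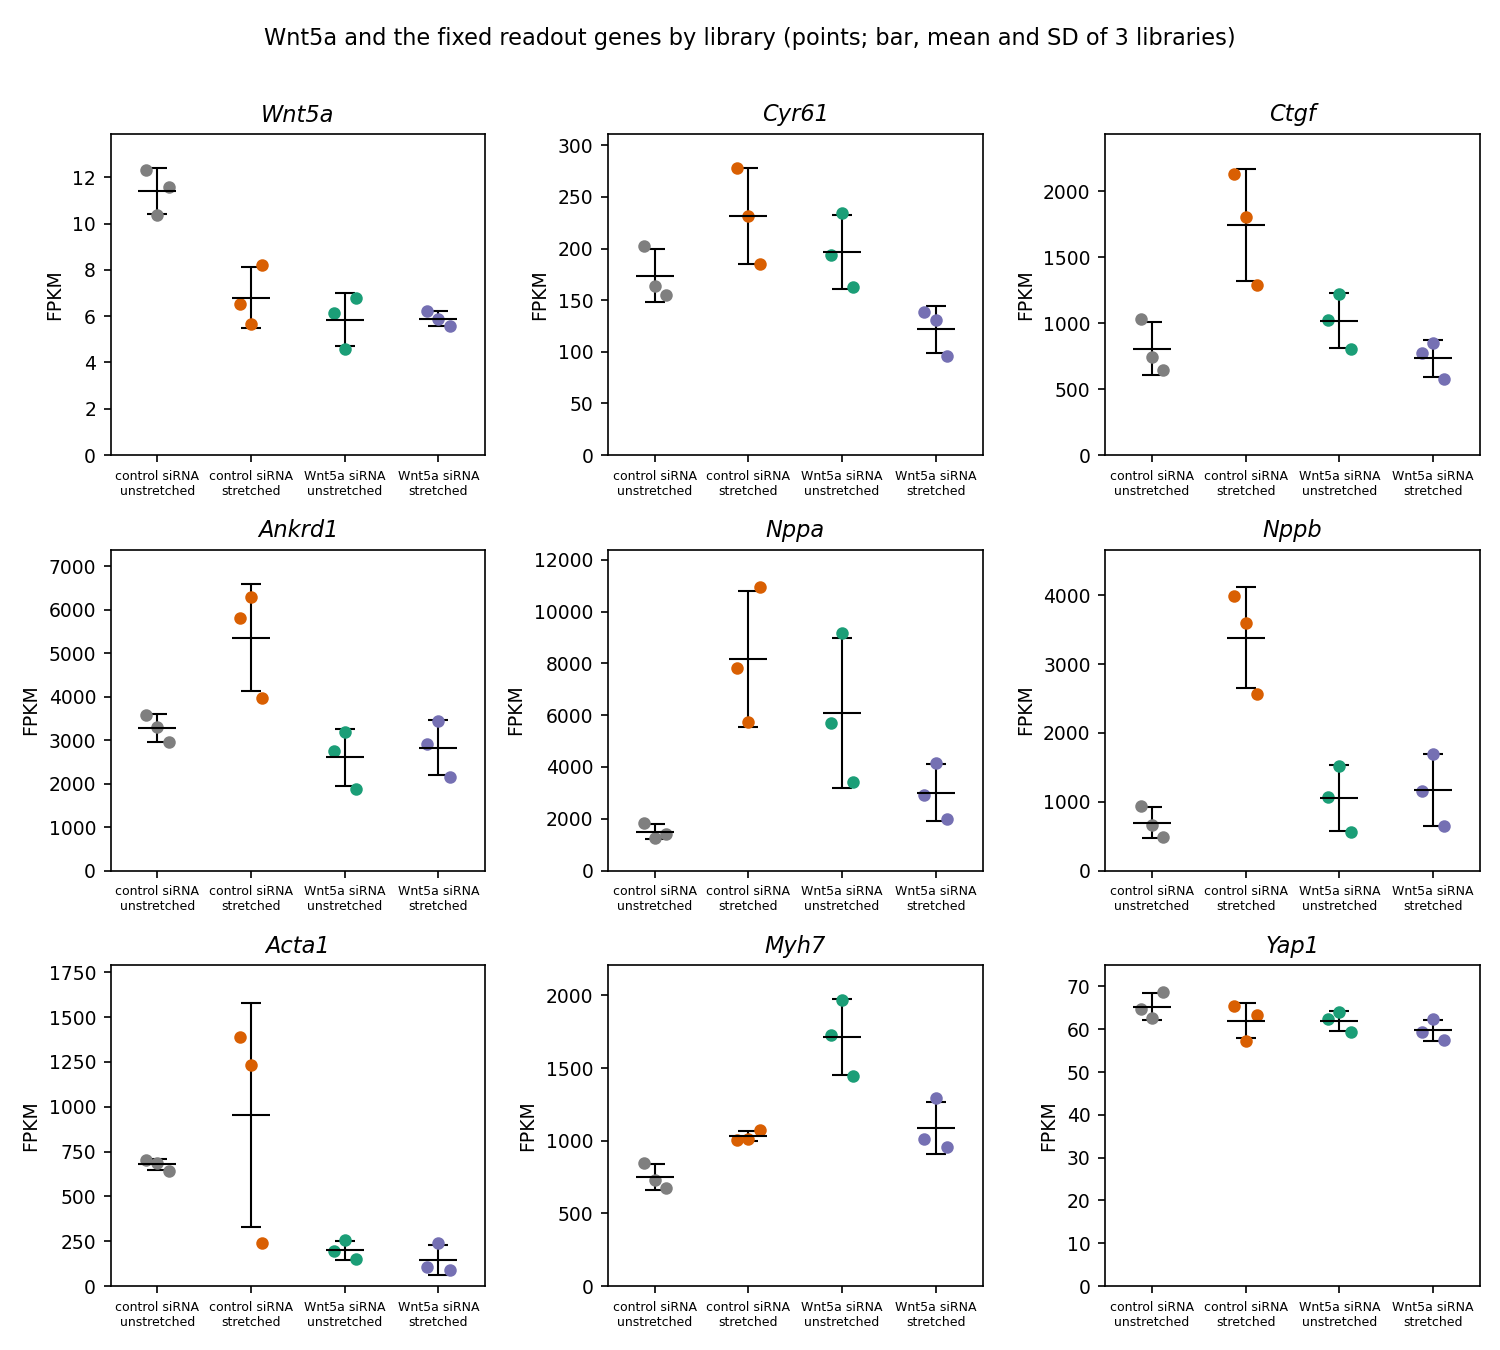
FPKM of Wnt5a and of the 8 fixed readout genes in each of the 12 libraries (points) with the mean and SD of each group of 3 (bars); the vertical axis is linear and starts at 0. Wnt5a was highest in the unstretched control libraries, at 10.4 to 12.3 FPKM, and Nppa was highest on average in the stretched control libraries, at 8177 ± 2620 FPKM.

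Of the libraries 1 stood apart from its group. Stretched control 3 scored −3.99 on the second principal component of log2(FPKM + 1), with 22.9% of the variance, against 25.1 and 24.8 for replicates 1 and 2. The SD of its log2 differences from these replicates was 0.393 and 0.426, against 0.205 to 0.288 for every other pair of replicates. Acta1, skeletal alpha-actin, was at 238 FPKM in stretched control 3 and at 1387 and 1235 in the other replicates. The following genes were chosen after their values were seen. Myh6, the alpha myosin heavy chain, was at 798 FPKM against 1823 and 2242, and Krt18, a keratin, at 15.9 against 69.9 and 74.8. Postn, a matrix protein of activated fibroblasts, was at 1667 FPKM against 607 and 625, and Lyz2, a lysozyme of macrophages, at 273 against 155 and 165. Counts of all changed genes are therefore also given without this library, and list counts where it or TPM scaling moves them by over 1.5 times and by 3 or more genes.

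Stretch with control siRNA addresses how cardiomyocytes with their own Wnt5a respond to mechanical load. Nppa, atrial natriuretic peptide, rose from 1495 ± 291 to 8177 ± 2620.1 FPKM, and Nppb, brain natriuretic peptide, from 698 ± 230.2 to 3386 ± 737 (log2 changes 2.42 ± 0.35 and 2.30 ± 0.39, adjusted p = 1.1e-04 and 3.3e-04). The largest rises were of Stmn4, a microtubule-binding stathmin (3.59, 1 unstretched control library being listed at 0), Bdkrb2, the bradykinin B2 receptor (3.41), Xirp2, an actin-binding protein of intercalated discs (2.97), Ramp3, an accessory protein of adrenomedullin receptors (2.55), and Tnc, tenascin C of the matrix (2.52). Their adjusted p ran from 1.5e-06 for Tnc to 1.1e-05 for Stmn4. Mir6326, a microRNA gene, stood first among the falls by the rule. It was listed at 537, 971 and 529 FPKM in the unstretched control and at 520, 0 and 0 in the stretched control libraries, and since a 0 can be a failed estimate, no change is drawn from it. The same holds for Rmrp, the RNA of RNase MRP, at 11.98, 6.502 and 14.2 FPKM in the unstretched and 0, 2.08 and 0 in the stretched control libraries. The largest other falls were of Smim5 (−3.00 ± 0.19), Tmem179 (−2.51 ± 0.29) and Hfe2, hemojuvelin (−2.44 ± 0.30). Of the 10518 genes tested 5711 changed, 2889 of them higher and 2822 lower, and 257 were higher and 469 lower by at least 2-fold. Without stretched control 3 the count was 6035. The libraries of the compared groups did not overlap in 58.0% of genes, against 10% by chance. TPM scaling, which was chosen after the data were seen and sets all libraries to the same sum, moved the median log2 change of all genes to −0.20 and gave 1455 higher and 4502 lower genes. With a pseudocount of 0.1 the log2 changes were 5.48 for Stmn4, 4.11 for Bdkrb2, −3.63 for Smim5, −4.31 for Tmem179 and −3.20 for Hfe2. That of Nppa was 1.73 after quantile normalization.

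Of the other fixed readouts, Ctgf (Ccn2), a target of the co-activator YAP, rose from 808 ± 199 to 1744 ± 423 FPKM (log2 change 1.11 ± 0.22, adjusted p = 0.0012). Ankrd1, a stress-responsive titin partner and YAP target, rose from 3281 ± 312 to 5357 ± 1228 (0.68 ± 0.22, adjusted p = 0.0201). Myh7, the slow myosin heavy chain, rose from 751 ± 86.9 to 1031 ± 35.4 (0.46 ± 0.13, adjusted p = 0.0101). Cyr61 (Ccn1), another YAP target, was at 174 ± 25.5 and 231 ± 46.4 FPKM (adjusted p = 0.0733) and Yap1 itself at 65.3 ± 3.10 and 62.0 ± 4.16 (adjusted p = 0.37). Acta1 was at 678 ± 31.9 and 953 ± 624 (adjusted p = 0.854), and none of these 3 passed limma's test. The log2 change of Acta1 was 0.13 ± 0.54. Without stretched control 3 it was 0.95 and passed (adjusted p = 0.0232, range 0.0232 to 0.917 over the alternatives). Ankrd1 did not pass after quantile normalization (adjusted p = 0.315), with TPM scaling (0.0697), or without stretched control 1 (0.0666) or 2 (0.0719) or unstretched control 3 (0.0697), within a range of 5.2e-04 to 0.315. Myh7 did not pass after quantile normalization (0.308) or with TPM scaling (0.123), within 0.0054 to 0.308, while Yap1 was called lower in these (0.0444 and 0.0016, range 0.0016 to 0.833). Cyr61 was called higher without unstretched control 1 (0.0444) or stretched control 3 (0.0182, range 0.0072 to 0.364).

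Gene lists fixed before the data were examined were tested with camera against all other genes. Members not counted as risen or fallen did not pass, and counts adjusted over the list alone are given where they differ. Of the fetal and hypertrophic marker genes 14 of 18 rose, or 14 and 1 adjusted over the list alone (camera adjusted p = 5.7e-04). They were led by Xirp2 and by Fhl1, a LIM protein of the sarcomere (2.11 ± 0.25). Immediate early genes, induced within minutes by many stimuli, followed, as 27 of 32 rose and 1 fell, or 28 and 1 adjusted over the list alone (adjusted p = 6.1e-07). Dusp6, an ERK phosphatase, changed by 1.54 ± 0.16 and Klf4 by 0.74 ± 0.09. Of the extracellular matrix genes 24 of 27 rose (adjusted p = 1.7e-07), including Tnc at 2.52 ± 0.18 and the protease inhibitor Timp1 at 1.09 ± 0.12. TGF-beta response genes rose in part, as 14 of 23 rose and 3 fell, or 16 and 3 adjusted over the list alone (adjusted p = 5.5e-04). Among them Bhlhe40 rose by 1.23 ± 0.11 and Id1 by 2.24 ± 0.21. Unfolded protein and ER stress genes (22 of 27 rose, adjusted p = 5.9e-08) were led by Atf4 (0.93 ± 0.06) and the chaperone Dnajc3 (45.0 ± 2.98 to 90.9 ± 9.42 FPKM, adjusted p = 3.6e-06). Heat shock and chaperone genes (14 of 21 rose, or 15 adjusted over the list alone, adjusted p = 5.5e-04) were led by Hspa8 (0.62 ± 0.07) and Hsph1 (0.61 ± 0.08), and 5 rose with TPM scaling. Every tested ribosomal protein gene rose (34 of 34, adjusted p = 2.4e-12), among them Rpl18 (0.58 ± 0.07) and Rpl13 (0.68 ± 0.08). With an estimated correlation between genes none of these 7 lists passed camera, at adjusted p = 0.496 with an estimated correlation for the immediate early and heat shock lists and 0.471 for the other 5.

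Other lists rose by narrower margins. Growth factor and paracrine genes moved both ways, as 13 of 28 rose and 6 fell, or 14 and 6 adjusted over the list alone (adjusted p = 0.0379, adjusted p = 0.586 with an estimated correlation). The neurotrophin Bdnf rose by 1.61 ± 0.15 and Gdf6 by 1.87 ± 0.17. Of the cholesterol biosynthesis genes 12 of 22 rose and 1 fell (adjusted p = 0.0106, adjusted p = 0.723 with an estimated correlation). An example was the epoxidase Sqle at 0.75 ± 0.12. Of the cell cycle genes 9 of 36 rose and 1 fell, or 2 and 0 adjusted over the list alone (adjusted p = 0.0325, adjusted p = 0.723 with an estimated correlation), led by Ccnd1, cyclin D1, at 1.87 ± 0.12. The median over the list was 0.17, which TPM scaling turned to −0.05 at adjusted p = 0.0701. Fibroblast markers (10 of 16 rose, or 11 adjusted over the list alone, adjusted p = 0.0223, adjusted p = 0.628 with an estimated correlation) included the matrix proteins Dpt at 0.62 ± 0.09 and Postn at 1.32 ± 0.29. Macrophage and leukocyte markers (9 of 16 rose, adjusted p = 0.0132, adjusted p = 0.687 with an estimated correlation) included Lyz2 at 1.40 ± 0.17 and Cd53 at 0.89 ± 0.17. The cell cycle list had 4 higher and 0 lower without stretched control 3. With TPM scaling 7 cholesterol, 1 cell cycle, 5 fibroblast and 3 macrophage genes were higher, and 2 cell cycle and 2 fibroblast genes lower. Without stretched control 3 adjusted p was 0.151 for cholesterol biosynthesis, 0.356 for cell cycle, 0.0522 for fibroblast and 0.0765 for macrophage genes. The cell cycle list also did not pass at a filter of FPKM 5 (0.0669) or without unstretched control 2 (0.069) or 3 (0.0877), and the fibroblast list after quantile normalization (0.105) or at FPKM 5 (0.0625). The growth factor list did not pass at FPKM 5 (0.19) or without unstretched control 3 (0.0677) or stretched control 1 (0.0595) or 2 (0.057). Over all alternatives adjusted p ran over 0.0011 to 0.151 for cholesterol biosynthesis, 0.0045 to 0.356 for cell cycle, 0.005 to 0.105 for fibroblast, 0.0011 to 0.0765 for macrophage and 0.0011 to 0.19 for growth factor genes. The log2 change of Bdnf was 2.38 with a pseudocount of 0.1.

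Genes of energy metabolism and excitation fell with stretch. Of the fatty acid oxidation genes 1 of 33 rose and 30 fell (camera adjusted p = 8.1e-10). The dehydrogenase Hadh went from 59.2 ± 8.44 to 11.1 ± 3.11 FPKM (−2.34 ± 0.20) and the carnitine transferase Cpt2 from 38.7 ± 1.20 to 17.0 ± 2.24 (−1.15 ± 0.11). Of the nuclear genes of oxidative phosphorylation 20 of 37 fell (adjusted p = 1.7e-04), such as Ndufs1 of complex I (−0.52 ± 0.08) and Cox8b of complex IV (−0.87 ± 0.16). Calcium handling and ion channel genes moved in 1 direction, as 22 of 33 fell, or 23 adjusted over the list alone (adjusted p = 1.2e-07). They were led by Cacna1c, the L-type calcium channel (−1.74 ± 0.09), and Kcnj11, a subunit of the ATP-sensitive potassium channel (−1.71 ± 0.12). Interferon response genes (1 of 33 rose and 20 fell, adjusted p = 1.7e-04) included Parp9 at −1.02 ± 0.09, the RNA sensor Ddx58 at −0.98 ± 0.11 and, higher, Ifitm3 at 0.80 ± 0.09. None of these 4 lists passed camera with its own correlation, at adjusted p = 0.687 with an estimated correlation for oxidative phosphorylation and 0.471 for the others. The falls stood beside higher markers of other cell types, with 10 of 16 fibroblast and 9 of 16 macrophage markers raised. With TPM scaling these were 5, with 2 lowered, and 3, and 36 of the oxidative phosphorylation genes fell.

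The remaining lists did not pass camera with control siRNA, although members changed. Of the YAP and TAZ target genes 7 of 20 rose and 3 fell, or 9 and 3 adjusted over the list alone (adjusted p = 0.288), with Gadd45a, a DNA damage response gene, at 1.16 ± 0.14 and the ligand Tgfb2 at 1.48 ± 0.21. Of the Hippo pathway components, the kinases and partners upstream of YAP, 3 of 18 rose and 6 fell (0.532). Of the SRF and MRTF target genes 12 of 28 rose and 6 fell (0.294), with the myosin kinase Mylk at −1.05 ± 0.09 and Tagln2 at 1.02 ± 0.10. Of the integrin and focal adhesion genes 12 of 23 rose and 3 fell, or 13 and 3 adjusted over the list alone (0.0993), and of the sarcomere genes 8 of 24 rose and 10 fell, or 8 and 12 adjusted over the list alone (0.463). Of the latter the stretch sensor Csrp3 was at 1.82 ± 0.21 and Tmod1, which caps thin filaments, at −0.65 ± 0.09. Among Wnt genes, of the noncanonical Wnt and planar polarity components 8 of 21 rose and 2 fell, or 7 and 1 adjusted over the list alone (0.559) and of the beta-catenin targets 4 of 11 rose and 3 fell (0.719). Among stress lists, of the inflammatory cytokine and NF-kB targets 8 of 19 rose and 3 fell, or 9 and 3 adjusted over the list alone (0.211), and of the NRF2 targets 10 of 26 rose and 5 fell (0.214). Likewise, of the p53 targets 8 of 25 rose and 6 fell (0.362), of the hypoxia genes 6 of 20 rose and 8 fell (0.745) and of the glycolysis genes 6 of 24 rose and 11 fell, or 7 and 11 adjusted over the list alone (0.39). Among cell type markers, of the smooth muscle and pericyte genes 3 of 13 rose and 3 fell (0.732) and of the endothelial 1 of 12 rose and 1 fell, or 0 and 1 adjusted over the list alone (0.778). As for the rest, of the epicardial and mesothelial 4 of 8 rose (0.311) and of the Schwann and neuronal 2 of 7 rose and 2 fell (0.848). Of the erythroid genes only Hbb and Hba1 were tested, too few for camera, and Hbb fell. The list of mitochondrially encoded genes was not analysed here. With TPM scaling 8 integrin genes were higher and 8 lower, and these counts were 7 and 7 for SRF, 6 and 6 for NF-kB, 3 and 10 for planar polarity, 6 and 10 for NRF2, 5 and 7 for p53, 0 and 10 for Hippo, 4 and 13 for sarcomere, 3 and 15 for glycolysis and 1 and 1 for epicardial genes. The integrin list passed without unstretched control 1 (0.0413) or stretched control 3 (0.0457). Quantile normalization gave adjusted p = 0.0296 for glycolysis and 0.0106 for sarcomere genes, while a filter at FPKM 5 gave 0.0385 for NF-kB and 0.0342 for beta-catenin targets.

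**Figure D2:**
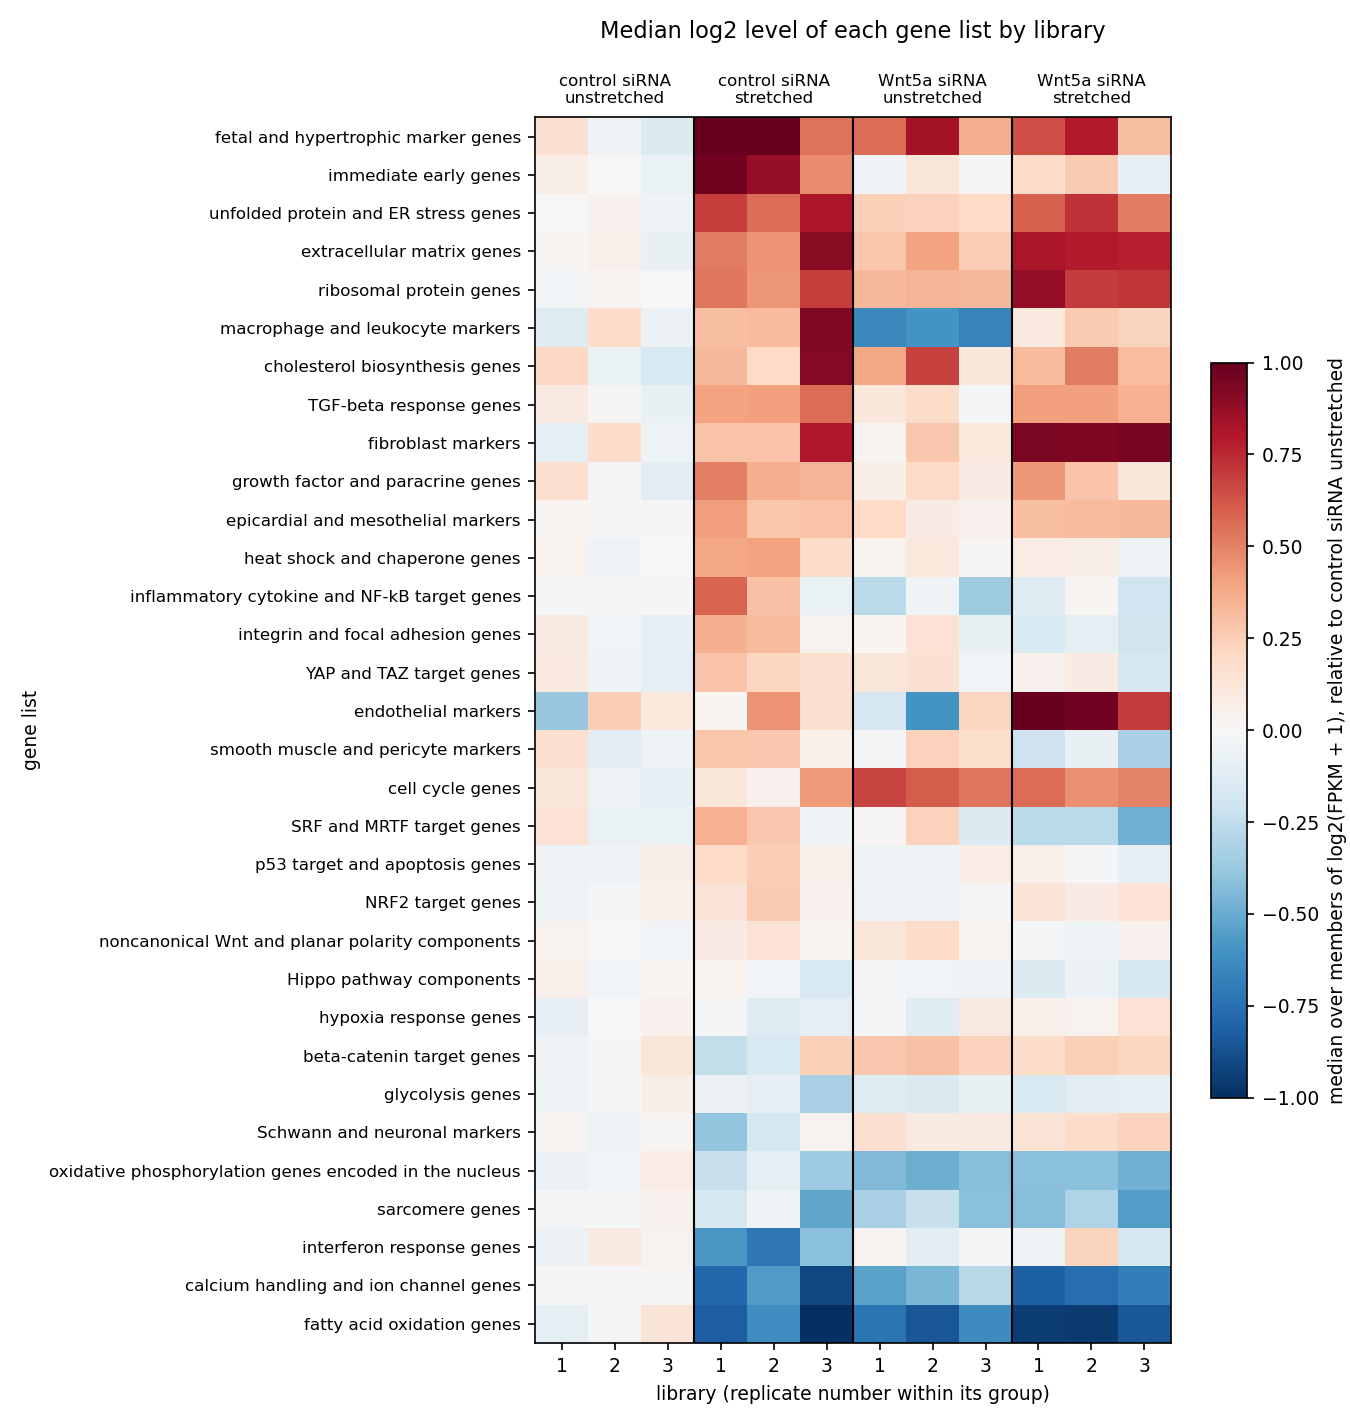
Heat map of the median log2 level of the tested members of each gene list in each of the 12 libraries, relative to the unstretched control group. With control siRNA the fatty acid oxidation list fell and all 34 ribosomal protein genes rose with stretch, and no list passed with an estimated correlation in any comparison.

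Wnt5a siRNA under stretch addresses which responses of stretched cells depend on Wnt5a, although Wnt5a itself did not differ detectably between these groups. All the fixed readouts that stretch had raised, except Myh7, were lower with the siRNA. Nppa was at 8177 ± 2620.1 FPKM in the stretched control and 3013 ± 1086 in the stretched Wnt5a siRNA group (log2 change −1.46 ± 0.35, adjusted p = 0.0114). Nppb was at 3386 ± 737 and 1166 ± 526 (−1.62 ± 0.39, adjusted p = 0.0114). The YAP target Ctgf fell (1744 ± 423 to 733 ± 142 FPKM, −1.24 ± 0.22, adjusted p = 0.0037), and so did Cyr61 (231 ± 46.4 to 122 ± 22.7, −0.92 ± 0.18, adjusted p = 0.0051) and Ankrd1 (5357 ± 1228 to 2831 ± 640.2, −0.92 ± 0.22, adjusted p = 0.0118). Acta1 fell from 953 ± 624 to 146 ± 81.4 FPKM (−2.48 ± 0.54, adjusted p = 0.008, and −3.29 without stretched control 3), with overlap between the libraries of the groups. Yap1, at 59.8 ± 2.47 FPKM with the siRNA (adjusted p = 0.59), and Myh7, at 1086 ± 180.2 (0.75), did not pass. Nppa (adjusted p = 0.0564), Nppb (0.0538) and Ankrd1 (0.0579) did not pass without stretched Wnt5a siRNA 3, nor Nppb (0.0532) and Ankrd1 (0.0543) without stretched control 1. Over the alternatives adjusted p ran over 0.0072 to 0.0564 for Nppa, 7.3e-04 to 0.0538 for Nppb and 7.3e-04 to 0.0579 for Ankrd1.

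After Rmrp, at 5.95, 10.7 and 14.4 FPKM with the siRNA and listed at 0 in stretched control 1 and 3, the largest rises with Wnt5a siRNA under stretch were of Car3, a muscle carbonic anhydrase (2.52 ± 0.31), the imprinted RNA H19 (2.04 ± 0.19) and G0s2, an inhibitor of triglyceride lipolysis (1.85 ± 0.18). The largest falls were of Bdkrb2 (−1.84 ± 0.31), Noct, nocturnin (−1.71 ± 0.29), Lmcd1, a LIM co-regulator in muscle (−1.65 ± 0.27), and Gadd45g (−1.63 ± 0.34). In all, 2875 of 10518 genes changed, 1386 higher and 1489 lower, of which 95 were higher and 86 lower by at least 2-fold. TPM scaling gave 2214 higher and 811 lower, with a median log2 change of 0.11. The count was 4668 without stretched control 3, 1102 without stretched control 1, 1648 without stretched control 2, 1268 without stretched Wnt5a siRNA 3 and 1707 without stretched Wnt5a siRNA 1. With only these 6 libraries in the fit it was 1208.

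Lists of rapid and contractile genes fell with Wnt5a siRNA under stretch. Of the immediate early genes 1 of 32 rose and 24 fell, or 2 and 24 adjusted over the list alone (camera adjusted p = 1.7e-09). The phosphatase Dusp1 was at −1.06 ± 0.13 and Junb at −0.86 ± 0.10 against a rise of Klf2 (0.73 ± 0.09). Of the SRF and MRTF targets 22 of 28 fell, or 23 adjusted over the list alone (adjusted p = 8.9e-09), led by Myl9, a regulatory myosin light chain (−1.03 ± 0.17), and Cnn1, calponin (−1.28 ± 0.23). Smooth muscle and pericyte markers, 4 of which other lists hold, did not pass as a list, with 8 of 13 lower, Cnn1 and Des among them, and 2 higher, or 8 and 4 adjusted over the list alone (adjusted p = 0.0564, range 0.0049 to 0.0926 over the alternatives). They passed with no filter (0.0356), at FPKM 5 (0.0389), with TPM scaling (0.0049) and without stretched control 2 (0.0382) or stretched Wnt5a siRNA 1 (0.0313). Integrin and focal adhesion genes fell too, as 1 of 23 rose and 15 fell (adjusted p = 5.6e-06), with Tns1, tensin, at −0.62 ± 0.11 and Itgb1bp2, melusin, at −0.75 ± 0.15. Of the heat shock genes 11 of 21 fell, or 15 adjusted over the list alone (adjusted p = 1.3e-05), led by Cryab (−0.87 ± 0.17) and Hspa1a (−0.92 ± 0.19). The fetal and hypertrophic list (1 of 18 rose and 11 fell, or 2 and 11 adjusted over the list alone, adjusted p = 0.0079) held Rcan1, a calcineurin regulator, at −1.60 ± 0.30 and, higher, Myl4, an atrial light chain, at 0.93 ± 0.12. Growth factor genes (3 of 28 rose and 13 fell, adjusted p = 0.0118) included Bdnf at −0.93 ± 0.15 and Inhba at −0.79 ± 0.13. These 6 lists had adjusted p = 0.504 with an estimated correlation. Inflammatory and NF-kB targets (7 of 19 fell, or 1 and 7 adjusted over the list alone, adjusted p = 0.0057, adjusted p = 0.315 with an estimated correlation) fell. They included Ptgs2, cyclooxygenase 2, at −1.39 ± 0.18 and the chemokine Cx3cl1 at −0.90 ± 0.14. Of the sarcomere genes 1 of 24 rose and 9 fell, or 2 and 9 adjusted over the list alone (adjusted p = 0.0038), led by Des, desmin (−1.20 ± 0.16). Of the oxidative phosphorylation genes 9 of 37 fell, or 11 adjusted over the list alone (3.4e-05), led by Ndufa4 (−0.99 ± 0.08), and both lists had adjusted p = 0.558 with an estimated correlation. Falls numbered 15 in the sarcomere and 26 in the oxidative phosphorylation list without stretched control 3, and with TPM scaling 2 of the latter fell and 1 rose. After quantile normalization adjusted p was 0.365 for oxidative phosphorylation (1.7e-07 to 0.365 over the alternatives) and 0.16 for sarcomere genes (7.4e-05 to 0.16), which also gave 0.0592 without stretched control 2. The log2 change of Hspa1a was −1.53 with a pseudocount of 0.1.

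Lists that rose with Wnt5a siRNA under stretch held interferon, ribosomal, cell cycle, endothelial and fibroblast genes. Of the interferon response genes 20 of 33 rose and 1 fell, or 23 and 2 adjusted over the list alone (adjusted p = 8.4e-08, adjusted p = 0.362 with an estimated correlation). The antiviral Bst2 was at 0.82 ± 0.11 and Oas1a at 1.11 ± 0.16. Of the ribosomal protein genes 14 of 34 rose, or 25 adjusted over the list alone (adjusted p = 1.2e-07, adjusted p = 0.513 with an estimated correlation), led by Rpl28 (0.31 ± 0.07). Of the cell cycle genes 14 of 36 rose and 1 fell, or 22 and 1 adjusted over the list alone (adjusted p = 3.7e-06, adjusted p = 0.503 with an estimated correlation). Thymidylate synthase Tyms was at 0.50 ± 0.12 and, against the list, Ccnd1 at −0.49 ± 0.12. Endothelial markers (4 of 12 rose and 1 fell, or 9 and 1 adjusted over the list alone, adjusted p = 0.0043, adjusted p = 0.503 with an estimated correlation) rose. They held the junction protein Cldn5 at 1.21 ± 0.22 and Egfl7 at 0.55 ± 0.13. Fibroblast markers (7 of 16 rose and 1 fell, or 7 and 2 adjusted over the list alone, adjusted p = 0.0118, adjusted p = 0.513 with an estimated correlation) held Pdgfrl at 0.92 ± 0.13 and Col3a1 at 0.77 ± 0.17. YAP and TAZ targets did not pass as a list, as 5 of 20 rose and 8 fell, or 5 and 11 adjusted over the list alone (adjusted p = 0.177, 0.0277 with TPM scaling, 0.0277 to 0.275 over the alternatives). Rises numbered 28 in the ribosomal and 26 in the cell cycle list without stretched control 3, and with TPM scaling 31 and 25. A filter at FPKM 5 took the endothelial list to adjusted p = 0.192 (range 9.0e-05 to 0.192), and leaving out stretched control 2 took the fibroblast list to 0.052 (range 2.6e-04 to 0.052). In a fit of only these 6 libraries Rpl28 (adjusted p = 0.0524, range 8.7e-04 to 0.0524), Col3a1 (0.0501, range 4.7e-06 to 0.0501) and Ccnd1 (0.0609) did not pass. Nor did Ccnd1 after quantile normalization (0.0708) or without stretched Wnt5a siRNA 3 (0.0543, range 0.005 to 0.0708). With a pseudocount of 0.1 the log2 change of Oas1a was 1.92.

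Wnt5a siRNA without stretch addresses what a lower Wnt5a transcript level does in resting cardiomyocytes. Nppa rose from 1495 ± 291 to 6089.8 ± 2894 FPKM (1.93 ± 0.35, adjusted p = 0.0024) and Myh7 from 751 ± 86.9 to 1714 ± 260.1 (1.18 ± 0.13, adjusted p = 3.4e-04). Acta1 fell from 704, 689 and 642 to 196, 255 and 149.5 FPKM (−1.79 ± 0.54, adjusted p = 0.0275). Nppb, at 1051 ± 479.8 FPKM with the siRNA (adjusted p = 0.334), and Ctgf, at 1018 ± 209 (0.276), did not pass. Neither did Cyr61, at 197 ± 36.0 (0.499), Ankrd1, at 2606 ± 663 (0.246), or Yap1, at 61.9 ± 2.33 (0.431). The largest rises were of Stmn4 (3.91 ± 0.37), Casq1, the calcium buffer of skeletal muscle (3.25 ± 0.34), Car3 (2.61 ± 0.31), the sodium channel subunit Scn3b (2.06 ± 0.20) and Myl4 (1.94 ± 0.12). Mir6326, at 537, 971 and 529 FPKM in the unstretched control, was listed at 0 in all 3 unstretched Wnt5a siRNA libraries. The next largest falls were of Gnb3, a G protein subunit (−1.94 ± 0.39), the lipid-binding Stard10 (−1.93 ± 0.31), the co-activator Cited1 (−1.92 ± 0.45) and Hfe2 (−1.83 ± 0.30). In all, 3002 genes changed, 1536 higher and 1466 lower, and 67 were higher and 96 lower by at least 2-fold. The count was 3935 without stretched control 3, 1774 without unstretched control 3, 1958 without unstretched control 2, 1865 without unstretched Wnt5a siRNA 1 and 1963 without unstretched Wnt5a siRNA 2. Acta1 (2.0e-04 to 0.0817 over the alternatives) did not pass with no filter (adjusted p = 0.0518) or without unstretched control 1 (0.0652), 2 (0.0693) or 3 (0.0683) or unstretched Wnt5a siRNA 1 (0.0717) or 3 (0.0817). With a pseudocount of 0.1 the log2 change of Stmn4 was 5.82.

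Lists of oxidative phosphorylation and fatty acid oxidation fell and cell cycle genes rose with Wnt5a siRNA in unstretched cells. Of the oxidative phosphorylation genes 33 of 37 fell, or 34 adjusted over the list alone (camera adjusted p = 5.1e-18, adjusted p = 0.487 with an estimated correlation). Ndufa4 went from 588 ± 16.1 to 186 ± 1.75 FPKM (−1.66 ± 0.08) and Cox8b was at −1.49 ± 0.16. Of the fatty acid oxidation genes 28 of 33 fell, or 29 adjusted over the list alone (adjusted p = 2.4e-15, adjusted p = 0.425 with an estimated correlation). The fatty acid transporter Cd36 was at −1.24 ± 0.14 and the carnitine carrier Slc25a20 at −1.01 ± 0.12. Calcium handling genes (3 of 33 rose and 14 fell, or 3 and 16 adjusted over the list alone, adjusted p = 6.0e-04, adjusted p = 0.516 with an estimated correlation) fell. They were led by Gja1, connexin 43 (−1.44 ± 0.12), and Cacna1c (−0.74 ± 0.09). Of the cell cycle genes 32 of 36 rose, or 33 adjusted over the list alone (adjusted p = 1.4e-15, adjusted p = 0.425 with an estimated correlation). The replication helicase Mcm3 was at 1.08 ± 0.12 and the ribonucleotide reductase Rrm2 at 0.68 ± 0.08. Of the ribosomal protein genes 26 of 34 rose, or 31 adjusted over the list alone (adjusted p = 2.1e-12, adjusted p = 0.541 with an estimated correlation), led by Rps23 (0.80 ± 0.13) and Rpl13 (0.44 ± 0.08). Unfolded protein genes (11 of 27 rose, adjusted p = 7.8e-04, adjusted p = 0.559 with an estimated correlation) were led by Chac1 (0.95 ± 0.15) and Trib3 (1.10 ± 0.23), both targets of ATF4. Of the extracellular matrix genes 12 of 27 rose, or 12 and 1 adjusted over the list alone (adjusted p = 0.0025, adjusted p = 0.724 with an estimated correlation). Among them were the collagen Col5a1 at 0.61 ± 0.10 and Loxl2, which links collagen, at 0.57 ± 0.10. Fetal and hypertrophic markers (8 of 18 rose and 1 fell, adjusted p = 0.002, adjusted p = 0.541 with an estimated correlation) were led by Myl4 and Myh7. Of the cholesterol biosynthesis genes 6 of 22 rose, or 10 adjusted over the list alone (adjusted p = 1.9e-04, adjusted p = 0.724 with an estimated correlation), with Fdps at 0.64 ± 0.17, and 14 rose without stretched control 3. Fdps did not pass without unstretched control 2 (0.0534) or 3 (0.0617) or unstretched Wnt5a siRNA 2 (0.0614, range 0.0049 to 0.0617).

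Macrophage and leukocyte markers fell with Wnt5a siRNA in unstretched cells, as 11 of 16 fell, or 13 adjusted over the list alone (adjusted p = 2.9e-05, adjusted p = 0.541 with an estimated correlation). The lysosomal Cd68 went from 31.2 ± 2.19 to 18.6 ± 1.23 FPKM (−0.71 ± 0.11) and Aif1 was at −1.12 ± 0.20. Of the inflammatory and NF-kB targets 2 of 19 rose and 6 fell, or 2 and 10 adjusted over the list alone (adjusted p = 0.0445, adjusted p = 0.425 with an estimated correlation). In front were the inhibitor Nfkbia (−0.88 ± 0.11) and the adhesion molecule Vcam1 (−1.20 ± 0.15). Sarcomere genes moved both ways, as 4 of 24 rose and 8 fell, or 4 and 9 adjusted over the list alone (adjusted p = 0.0464, adjusted p = 0.844 with an estimated correlation). Myl4 and Myh7 were higher and Nebl, a thin filament protein, was at −1.53 ± 0.25. YAP and TAZ targets did not pass as a list (5 of 20 rose, adjusted p = 0.47), with the receptor kinase Axl at 0.35 ± 0.07 and Myof, myoferlin, at 0.41 ± 0.09. The NF-kB list (0.0131 to 0.199 over the alternatives) did not pass with no filter (0.102), at FPKM 5 (0.199) or without unstretched control 1 (0.069), unstretched Wnt5a siRNA 3 (0.0794) or stretched control 2 (0.055) or 3 (0.0998). The sarcomere list (0.0085 to 0.132) did not pass at FPKM 5 (0.0611), after quantile normalization (0.0598), without a trend (0.0519) or without unstretched control 1 (0.0734) or 3 (0.0762), unstretched Wnt5a siRNA 3 (0.132) or stretched Wnt5a siRNA 3 (0.0525).

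Stretch with Wnt5a siRNA addresses what mechanical load does when Wnt5a is targeted. The largest rises were of genes of other cell types, Fbln1, a fibroblast matrix protein (4.65 ± 0.571 to 28.1 ± 3.42 FPKM, 2.37 ± 0.24), Emcn, an endothelial sialomucin (2.06 ± 0.52), and Dcn, decorin (100.2 ± 10.5 to 393 ± 36.2 FPKM, 1.96 ± 0.14). Next came Cdh5, the cadherin of endothelial junctions (1.86 ± 0.36), and Tm4sf19 (1.79 ± 0.18). The largest falls were of Myh11, smooth muscle myosin (38.2 ± 7.62 to 7.41 ± 1.18 FPKM, −2.21 ± 0.18), the olfactory receptor Olr59 (−1.74 ± 0.28), Corin, which processes natriuretic peptide (−1.66 ± 0.22), Myl7, an atrial light chain (−1.64 ± 0.46), and Fxyd7 (−1.58 ± 0.13). Of the readouts, Myh7 fell from 1714 ± 260.1 to 1086 ± 180.2 FPKM (−0.66 ± 0.13, adjusted p = 0.0057) and Cyr61 from 197 ± 36.0 to 122 ± 22.7 (−0.69 ± 0.18, adjusted p = 0.0209). Nppa, from 6089.8 ± 2894 to 3013 ± 1086 FPKM (adjusted p = 0.0806), and Nppb (0.824), Ctgf (0.174), Ankrd1 (0.742), Acta1 (0.529) and Yap1 (0.654) did not pass. With the replicate number as a block Ctgf was called lower (−0.47, adjusted p = 0.0239, range 0.0239 to 0.438). In all, 1686 genes changed, 888 higher and 798 lower, and 87 were higher and 39 lower by at least 2-fold. TPM scaling moved the median log2 change to −0.12 and gave 497 higher and 1759 lower. Nppa was called lower after quantile normalization (adjusted p = 0.0118), with TPM scaling (0.0353) and without stretched control 3 (0.0484) or unstretched Wnt5a siRNA 3 (0.0266, range 0.0118 to 0.265). The count was 2625 without stretched control 3, 849 without stretched Wnt5a siRNA 1, 1073 without stretched Wnt5a siRNA 2, 945 without unstretched Wnt5a siRNA 1 and 1114 without unstretched Wnt5a siRNA 3. Cyr61 did not pass without stretched Wnt5a siRNA 3 (adjusted p = 0.0793, range 0.0023 to 0.0831) or unstretched Wnt5a siRNA 1 (0.0634) or 2 (0.0831), nor Emcn without stretched Wnt5a siRNA 1 (0.0904, range 0.0132 to 0.0904) or unstretched Wnt5a siRNA 2 (0.0502). Myl7 did not pass with no filter (0.0558, range 0.0026 to 0.106) or without stretched Wnt5a siRNA 2 (0.104) or 3 (0.106) or unstretched Wnt5a siRNA 1 (0.0824), 2 (0.0813) or 3 (0.0673).

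Markers of other cell types rose as lists when cells with Wnt5a siRNA were stretched. Of the macrophage and leukocyte markers 14 of 16 rose (camera adjusted p = 1.2e-10), with Cd68 at 0.98 ± 0.11 and Lyz2 at 1.47 ± 0.17. Of the fibroblast markers 8 of 16 rose and 1 fell, or 10 and 1 adjusted over the list alone (adjusted p = 1.5e-06), with Dcn, Dpt at 1.09 ± 0.09 and Fbln1 in front. Of the endothelial markers 7 of 12 rose, or 8 and 1 adjusted over the list alone (adjusted p = 4.8e-05), with Cldn5 at 1.39 ± 0.22 and the receptor Tie1 at 1.42 ± 0.24. Smooth muscle and pericyte markers fell, as 2 of 13 rose and 7 fell, or 2 and 9 adjusted over the list alone (adjusted p = 0.0118), led by Myh11 against a rise of Kcnj8 (0.67 ± 0.15). Beside them, ribosomal protein genes (33 of 34 rose, or 34 adjusted over the list alone, adjusted p = 4.6e-24) rose, with Rpl28 at 0.52 ± 0.07. So did unfolded protein genes (15 of 27 rose, or 16 adjusted over the list alone, adjusted p = 4.2e-09), with the chaperone Hspa5 at 0.73 ± 0.09. Matrix genes rose as well (16 of 27 rose and 1 fell, or 17 and 1 adjusted over the list alone, adjusted p = 7.7e-09), with the protease Mmp2 from 229 ± 9.27 to 458 ± 12.1 FPKM (adjusted p = 7.8e-05) and Thbs2 at 1.07 ± 0.10. Calcium handling genes fell, as 1 of 33 rose and 14 fell, or 1 and 17 adjusted over the list alone (adjusted p = 4.2e-07), with Kcnj11 at −0.84 ± 0.12 and Cacna1c at −0.65 ± 0.09. SRF and MRTF targets fell too (9 of 28 fell, or 1 and 13 adjusted over the list alone, adjusted p = 6.8e-06), with Mylk at −0.88 ± 0.09 and Lmod1 at −1.29 ± 0.14. TGF-beta response genes (6 of 23 rose and 2 fell, or 7 and 2 adjusted over the list alone, adjusted p = 0.0118) included the Smad targets Id2 (1.02 ± 0.11) and Id3 (0.94 ± 0.17). NF-kB targets (4 of 19 rose, or 7 adjusted over the list alone, adjusted p = 0.0118) included the chemokines Ccl2 (48.6 ± 4.42 to 98.4 ± 11.2 FPKM, adjusted p = 3.2e-04) and Ccl7 (0.74 ± 0.14). Of the sarcomere genes 8 of 24 fell (adjusted p = 0.0118), led by Myl4 (−1.29 ± 0.12) and Myh7. Of the integrin genes 1 of 23 rose and 2 fell (adjusted p = 0.0438), or 0 adjusted over the list alone by limma, with 7 at an unadjusted p under 0.05. Of these 13 lists none passed with an estimated correlation. The lowest was adjusted p = 0.256 with an estimated correlation for the macrophage, ribosomal, unfolded protein, calcium, fibroblast and NF-kB lists. The next were 0.318 for matrix, 0.333 for endothelial and smooth muscle, 0.555 for SRF and TGF-beta and 0.743 for sarcomere and integrin genes. Of the YAP and TAZ targets 2 of 20 rose and 2 fell, or 2 and 3 adjusted over the list alone (adjusted p = 0.393). Of NF-kB targets 7 rose, of integrin genes 6 fell, and of YAP targets 3 rose and 6 fell without stretched control 3. With TPM scaling 15 SRF targets and 8 integrin genes fell and 0 of both rose, and 1 YAP target rose and 5 fell. The TGF-beta list did not pass without unstretched Wnt5a siRNA 3 (0.062, range 0.0025 to 0.062), the NF-kB list with no filter (0.0866, range 0.0016 to 0.0866) and the sarcomere list without stretched Wnt5a siRNA 3 (0.13, range 2.8e-05 to 0.13). The integrin list (range 0.0027 to 0.305) did not pass without a trend (0.0623) or without unstretched Wnt5a siRNA 1 (0.0573) or 2 (0.305) or stretched Wnt5a siRNA 1 (0.0537) or 3 (0.175). With a pseudocount of 0.1 the log2 changes were −2.53 for Olr59 and 2.13 for Cldn5, and that of Emcn was 2.73.

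The interaction, the stretch change with Wnt5a siRNA minus that with control siRNA, tests directly whether the response to load depends on the siRNA. The difference was negative for Nppa (−3.38 ± 0.49 on the log2 scale, adjusted p = 0.0017), Nppb (−2.15 ± 0.55, adjusted p = 0.016), Ctgf (−1.58 ± 0.31, adjusted p = 0.0054), as it was for Cyr61 (−1.09 ± 0.25, adjusted p = 0.0104) and Myh7 (−1.12 ± 0.19, adjusted p = 0.0026). Ankrd1 (0.212), Acta1 (0.543) and Yap1 (0.881) did not pass. The largest negative differences were of Stmn4 (−3.82 ± 0.53), Nppa, Bdkrb2 (−2.89 ± 0.44), Xirp2 (−2.75 ± 0.36) and the growth factor Hbegf (−2.46 ± 0.44). After Mir6326 and Rmrp, for which only levels are given, the largest positive ones were of the nuclear receptor Nr0b2 (2.35 ± 0.45), Doc2g (2.31 ± 0.50) and Smim5 (2.27 ± 0.27). Mir6326 was listed at 889, 955 and 0 FPKM in the stretched Wnt5a siRNA libraries, and Rmrp at 5.97, 10.01 and 10.3 in the unstretched ones. In all, 2503 genes differed, 1226 with a positive and 1277 with a negative difference, and TPM scaling gave 1607 positive and 815 negative with a median of 0.10. The count was 3638 without stretched control 3, 1574 without stretched Wnt5a siRNA 3 and 1612 without unstretched control 3. With a pseudocount of 0.1 the differences were −5.72 for Stmn4 and −3.49 for Bdkrb2. That of Acta1, −0.69 ± 0.77, was −1.51 without stretched control 3 and then passed (adjusted p = 0.0179, range 0.0179 to 0.858).

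Of the 16 lists called for stretch with control siRNA, camera called the interaction of 12 in the opposite direction, and of macrophage markers in the same direction. Fatty acid oxidation genes had positive differences, as 21 of 33 were positive, or 24 adjusted over the list alone (adjusted p = 5.7e-11), with Hadh at 2.11 ± 0.28 and Cpt2 at 1.05 ± 0.15. So did oxidative phosphorylation genes (11 of 37 were positive, or 12 adjusted over the list alone, adjusted p = 1.5e-06), led by Cox8b (1.43 ± 0.23), and interferon response genes (16 of 33 were positive, or 18 adjusted over the list alone, adjusted p = 1.5e-06), led by Parp9 (0.85 ± 0.12). Calcium handling genes were also positive on balance (11 of 33, or 12 adjusted over the list alone, adjusted p = 2.2e-04), led by Cacna1c (1.08 ± 0.13). Fetal and hypertrophic markers had negative differences (12 of 18, adjusted p = 2.9e-06), led by Xirp2. So did immediate early genes (13 of 32, or 16 adjusted over the list alone, adjusted p = 1.1e-06). Junb was at −0.95 ± 0.15 and Dusp6 at −1.23 ± 0.23. SRF and MRTF targets followed (1 of 28 was positive and 15 negative, or 1 and 18 adjusted over the list alone, adjusted p = 4.7e-06), led by Cnn1 (−2.31 ± 0.33). Then came heat shock genes (7 of 21 were negative, or 9 adjusted over the list alone, adjusted p = 1.0e-04), led by Hsph1 (−0.50 ± 0.11), and unfolded protein genes (10 of 27 were negative, adjusted p = 2.5e-04), led by Atf4 (−0.67 ± 0.09). Negative differences were also called for cell cycle genes (5 of 36 were negative, adjusted p = 3.0e-04), led by Ccnd1 (−0.98 ± 0.17), and integrin genes (1 of 23 was positive and 8 negative, or 1 and 9 adjusted over the list alone, adjusted p = 4.1e-04). So were they for TGF-beta genes (3 of 23 were positive and 11 negative, or 4 and 12 adjusted over the list alone, adjusted p = 0.0076), led by Bhlhe40 (−1.08 ± 0.16). The last were growth factor genes (2 of 28 were positive and 10 negative, adjusted p = 0.0158) and cholesterol biosynthesis genes (6 of 22 were negative, adjusted p = 0.0011), led by Hsd17b7 (−1.14 ± 0.24). Positive differences were called for endothelial markers (5 of 12 were positive, or 8 adjusted over the list alone, adjusted p = 0.0067) and for macrophage markers (adjusted p = 0.0256). Of the latter 1 of 16 was positive by limma, or 0 adjusted over the list alone, with 3 at an unadjusted p under 0.05. Of the YAP and TAZ targets 3 of 20 were positive and 5 negative, or 3 and 8 adjusted over the list alone (adjusted p = 0.0489), led by Tgfb2 (−1.52 ± 0.30), and this call was lost in 12 of 20 alternatives (0.0151 to 0.0796). None of these 17 lists passed with an estimated correlation (adjusted p = 0.47 to 0.633).

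Several of these list calls rested on single settings or libraries. The YAP and TAZ list did not pass with a pseudocount of 0.1 (0.0501), after quantile normalization (0.0628) or without a trend (0.0575). Nor did it without any 1 of the libraries (0.0509 to 0.0796), except unstretched control 1, unstretched Wnt5a siRNA 3 and stretched Wnt5a siRNA 2. The difference was negative for 15 heat shock, 23 immediate early, 13 integrin, 9 YAP and 3 calcium genes and positive for 7 macrophage, 1 integrin, 4 YAP and 13 calcium genes without stretched control 3. With TPM scaling it was positive for 19 oxidative phosphorylation and 1 cell cycle genes and negative for 2 cell cycle and 6 unfolded protein genes. Without stretched control 3 adjusted p was 0.0597 for cholesterol biosynthesis (range 5.5e-05 to 0.0597) and 0.055 for TGF-beta genes (range 0.0017 to 0.055). Smooth muscle and pericyte markers, with 5 of 13 negative, Cnn1 among them, did not pass (adjusted p = 0.0641, range 0.0171 to 0.0914) but did with no filter (0.0493), at FPKM 5 (0.0435), with TPM scaling (0.0171) and without unstretched Wnt5a siRNA 3 (0.0442) or stretched Wnt5a siRNA 1 (0.046). The macrophage list (range 1.9e-04 to 0.104) did not pass without unstretched control 2 (0.0862) or stretched control 1 (0.104) or 2 (0.101), and the growth factor list (range 0.0018 to 0.063) at FPKM 5 (0.063).

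The stretch response with Wnt5a siRNA lay mostly in the direction of that with control siRNA. Of the 5711 genes changed by stretch with control siRNA, 79.5% went in the same direction with Wnt5a siRNA. A line through 0 had a slope of 0.273, from 0.243 to 0.334 with each library left out. Picking genes by their change with control siRNA lowers this slope by itself. Over the genes called with Wnt5a siRNA the slope of the control on the Wnt5a siRNA response was 0.903. Of the 5711 genes 1224 were called in the same direction with Wnt5a siRNA (643 without stretched Wnt5a siRNA 1, 781 without 2, and 727 and 755 without unstretched Wnt5a siRNA 1 and 3) and 38 in the opposite direction (9 to 143 with each library left out, the highest without stretched control 3). The interaction was called for 2294 (1476 without stretched Wnt5a siRNA 3, 1486 without unstretched control 3). Both Nppa and Nppb were among 956 genes raised by stretch with control siRNA and lower with Wnt5a siRNA under stretch, against 409 for independent lists. Another 795 genes were lowered by stretch and higher with the siRNA, against 372. These comparisons share the stretched control libraries. In 100 simulations with no effect the covariance of the log2 changes was −0.0109 on average and −0.0180 at the lowest, against −0.104 observed. Pearson's r across genes, which are not independent replicates, was −0.518, inside the simulated range of −0.621 to −0.217. With 3 shared libraries the controls cannot be split, so part of the excess may come from them. The overlap of 956 was 1506 without stretched control 3, 400 without stretched control 1, 605 without stretched control 2 and 467 without stretched Wnt5a siRNA 3. It was 450 with only the libraries compared and 410 with TPM scaling. In these 6 settings that of 795 was 1289, 319, 511, 347, 341 and 1496, and 524 without stretched Wnt5a siRNA 1.

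Stretch and Wnt5a siRNA moved many genes in the same direction when each was applied alone. Nppa, Myh7, Stmn4 and Myl4 were higher with the siRNA in unstretched cells, and all but Myl4 also rose with stretch. Both raised 1003 genes, against 422 for independent lists, and both lowered 976, such as Cacna1c and Cox8b, against 393, while 112 went in opposite directions (35 without unstretched control 2 to 364 without stretched control 3). Those raised were 603 and 630 without unstretched control 3 and 2 and 638 without unstretched Wnt5a siRNA 1, and those lowered 560 without unstretched control 3. The shared unstretched control libraries gave a simulated covariance of 0.0109 on average and 0.0192 at most in 100 simulations, against 0.121 observed. Pearson's r across genes was 0.586, inside the simulated range of 0.259 to 0.645.

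**Figure D3:**
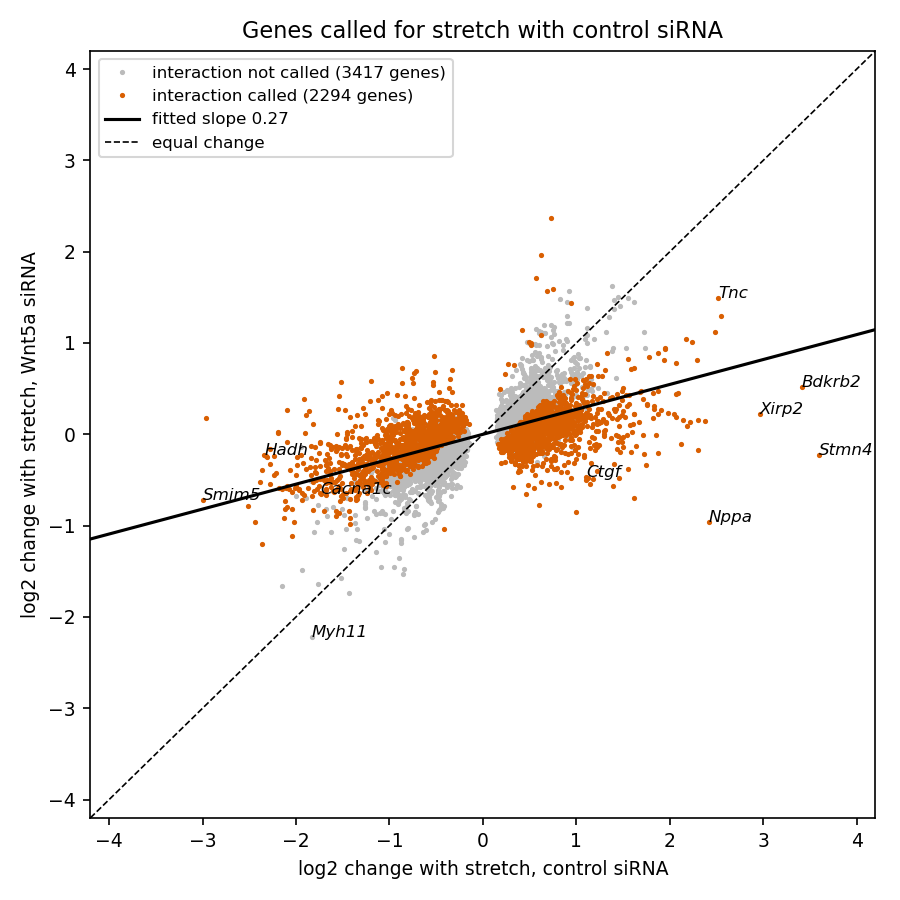
Log2 change of FPKM + 1 with stretch for each gene called with control siRNA (points), with control siRNA on the horizontal and Wnt5a siRNA on the vertical axis, coloured by whether the interaction was called; the lines are the fitted line and that of equal change. The fitted line had a slope of 0.273, and 2294 of the 5711 genes had a called interaction.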

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

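The 5 tests of explanations for the 3 patterns weighed here were chosen after the results were seen, while the counts over other splits of the samples were planned. The genes and lists that come first are those whose change with stretch differed between the siRNAs by the interaction test, with limma for genes and camera for lists. Values are the log2 change with Wnt5a siRNA minus that with control siRNA.

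Among the fixed readouts the difference was 0.70 for Wnt5a, −3.38 for Nppa, −2.15 for Nppb, −1.58 for Ctgf, −1.09 for Cyr61 and −1.12 for Myh7. Among the largest differences, negative values were those of Stmn4 (−3.82), Bdkrb2 (−2.89), Xirp2 (−2.75) and Hbegf (−2.46), and positive values those of Nr0b2 (2.35), Doc2g (2.31) and Smim5 (2.27). Among list members, positive values were 2.11 for Hadh, 1.05 for Cpt2, 1.43 for Cox8b, 0.85 for Parp9 and 1.08 for Cacna1c. Negative list members were Junb (−0.95), Dusp6 (−1.23), Cnn1 (−2.31), Hsph1 (−0.50), Atf4 (−0.67), Ccnd1 (−0.98), Bhlhe40 (−1.08), Hsd17b7 (−1.14) and Tgfb2 (−1.52). Of the clock genes, chosen after their values were seen, Arntl was at −0.51, Ciart at −1.33, Nr1d1 at −0.61 and Dbp at 0.81. The difference of Wnt5a did not pass without stretched control 1, unstretched control 1 or 3, stretched Wnt5a siRNA 1 or unstretched Wnt5a siRNA 2 (adjusted p = 0.0514 to 0.0559), within 0.0048 to 0.0559 over the alternatives. A pseudocount of 0.1 gave −5.72 for Stmn4.

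Median differences over lists were positive for endothelial markers (1.0), fatty acid oxidation (0.68), interferon response (0.60), macrophage markers (0.42), calcium handling (0.41) and oxidative phosphorylation (0.26). They were negative for fetal and hypertrophic markers (−1.13), immediate early genes (−0.67), SRF and MRTF targets (−0.53), cholesterol biosynthesis (−0.53), TGF-beta response (−0.46), growth factors (−0.43), integrins (−0.40), unfolded protein (−0.38), heat shock (−0.37), YAP and TAZ targets (−0.36) and the cell cycle (−0.31). Without stretched control 3 the adjusted p of camera was 0.0597 for cholesterol biosynthesis, 0.055 for TGF-beta and 0.0516 for YAP and TAZ genes. The YAP and TAZ list was also lost without most other single libraries, at 0.0509 to 0.0796. Macrophage markers did not pass without stretched control 1 (0.104) or 2 (0.101) or unstretched control 2 (0.0862).

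Stretched control 3 lay apart from replicates 1 and 2 of its group, and without it Wnt5a siRNA under stretch changed 4668 genes in place of 2875. Fewer cardiomyocytes in this library, as sole cause, would raise markers of all other cell types alike. Against replicates 1 and 2 its macrophage markers were higher by 0.626 on average (SE 0.0597 over 16 genes). Fibroblast markers were higher by 0.451 (SE 0.133 over 16, 3 in another list). Endothelial markers were at −0.0761 (SE 0.0930 over 12), a gap of 0.702 (SE 0.111) between highest and lowest. Of the most abundant, the stretched control group held Lyz2 at 198 ± 65.3, Col1a1 at 2277 ± 634 and Flt1 at 15.2 ± 1.80 FPKM. With 1 library, SE over genes and low endothelial levels, fewer cardiomyocytes stay possible. A stretched Wnt5a siRNA library under this label, or a mixture of both groups, would lie between them, as its median position of 0.580 over 378 genes does (0 at replicates 1 and 2, 1 at the stretched Wnt5a siRNA mean), but its macrophage markers were above those in each of the other 5 stretched libraries, by at least 0.572 (SE 0.0939) where those 5 spanned 0.172, and Nppa was at 10954 FPKM against 7829 and 5749 in replicates 1 and 2 and 1976 to 4141 with the siRNA. A sample from outside these groups, more macrophages and fibroblasts in this culture, or a different response of its cells stay open and were not tested.

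Wnt5a siRNA without stretch moved genes in the direction of stretch, with 1003 genes raised and 976 lowered by both (603 and 560 without unstretched control 3). Spread among the shared unstretched control libraries gave a covariance of at most 0.0192 in 100 simulations with no effect. The 0.121 observed argues against spread as the whole cause, but not against a shift common to these libraries. Fewer cardiomyocytes on both occasions, as the whole cause, would raise the markers of all other cell types. The 16 macrophage markers, which no other list holds, were instead at −0.607 on average (SE 0.0826) with the siRNA. Lyz2 was at 72.3 ± 11.5 and 78.5 ± 3.94 FPKM and Tyrobp at 32.2 ± 6.01 and 18.4 ± 1.36 without and with it. Fibroblast markers moved both ways, with 5 of 16 raised and 3 lowered, although the most abundant, Col1a1 and Col3a1, were at 1609 ± 33.7 and 1177 ± 92.9 FPKM without and 2426 ± 53.2 and 1791 ± 73.8 with it. A fall of the macrophage list for other reasons would hide such a rise, so fewer cardiomyocytes stay possible as part of the cause. A response common to less Wnt5a and load may be behind the pattern and was not tested, nor were other effects of the siRNA.

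Stretch with Wnt5a siRNA raised markers of fibroblasts (0.734 on average, SE 0.188 over 16 genes), macrophages (0.863, SE 0.0786 over 16) and endothelial cells (0.969, SE 0.220 over 12). Fewer cardiomyocytes after stretch, as the whole cause, would also raise smooth muscle and pericyte markers, but the 9 of these in no other muscle list were at −0.386 on average (SE 0.296), 1.12 (SE 0.350) below fibroblast markers. As they went both ways (Myh11 at −2.21, Rgs5 at 0.70 and Kcnj8 at 0.67), this does not decide the cause. Without Myh11 their mean was −0.157 (SE 0.213), 0.892 (SE 0.284) below. Of the most abundant genes, Col1a1 went from 2426 ± 53.2 to 3327 ± 209 FPKM, Lyz2 from 78.5 ± 3.94 to 219 ± 14.5, Acta2 from 2766 ± 632 to 1763 ± 158 and, against its list, Flt1 from 13.9 ± 2.82 to 10.6 ± 1.03. A loss of cardiomyocytes, alone or with smooth muscle cells, growth of the other cells, or gene regulation by stretch with Wnt5a siRNA stay open and were not tested.

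Other splits of the samples were fitted in the same way. With 6 libraries in 10 splits they are too few for a share under 0.05. Stretch with control siRNA called 5711 genes and the highest other split 1, Wnt5a siRNA under stretch 2875 against 2, Wnt5a siRNA without stretch 3002 against 0 and stretch with Wnt5a siRNA 1686 against 0, all by limma. For the interaction, with 2503 genes, the siRNA labels were redrawn within unstretched and within stretched libraries, in 100 of 200 possible splits, the real one included. These do not decide whether chance gave the interaction, because redrawing also breaks up the effect of the siRNA itself, and all 99 others had a wider residual spread (median variance of a gene 0.0223 or more, against 0.0180), which loses calls with or without an interaction. The split that mirrors the labels in stretched libraries alone was not among them. The highest other, 1987 genes, kept the unstretched groups and put stretched control 3 with stretched Wnt5a siRNA 1 and 2, which points to a structure of the samples around that library.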

How the results depend on the processing

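TPM scaling was chosen after the data were seen, and the other settings were planned. Of 4572 recomputed values of named genes 4509 kept their side of the threshold, 46 were no longer called, 17 were newly called and 0 reversed a called direction. The direction of values that were called in neither setting was not compared. The median of the cell cycle list for stretch with control siRNA, 0.17, was −0.05 with TPM scaling. At 1.5-fold or more the calls were 2368, 864, 905, 553 and 1338, fewer because the criterion is stricter. The order is stretch with control siRNA, Wnt5a siRNA under stretch, Wnt5a siRNA without stretch, stretch with Wnt5a siRNA and the interaction. With only the libraries compared, Wnt5a siRNA under stretch called 1208 genes, 1187 of them among the 2875. Stretch with control siRNA then called 4734, but Wnt5a siRNA without stretch 3678 and stretch with Wnt5a siRNA 2260. The overlap of genes raised by stretch and lower with the siRNA was then 450 in place of 956. With TPM scaling, which lowered the median change with stretch by construction and raised that with the siRNA under stretch, this overlap was 410. Camera with an estimated correlation called 0 lists in each comparison, with 2, 2, 3, 6 and 2 at an unadjusted p under 0.05. In the same order the preset called 16, 14, 12, 13 and 17. Fry, which does not compare a list with other genes, called 21, 15, 12, 10 and 15. With 1 library left out the calls ran, in that order, over 4830 to 6035, 1102 to 4668, 1774 to 3935, 849 to 2625 and 1574 to 3638. The overlap ran from 400 to 1506. The highest of each came without stretched control 3. Wnt5a siRNA without stretch and stretch with Wnt5a siRNA do not compare that library, so there it acts through the common estimate of the spread. Other causes were not tested. In all other settings these counts stayed within 1.5 times.

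The replicate number as a block gave 5710, 2928, 3093, 1693 and 2566 calls in the same order. Of the 18 pairs of libraries with the same number 9 had deviations from the group means that correlated above 0.1, so that the numbers were not taken to pair the libraries, except in stretch with Wnt5a siRNA, where all 3 pairs were above it. Of named readouts the block also called Cyr61 for stretch with control siRNA (0.40, adjusted p = 0.0072, range 0.0072 to 0.364 over the alternatives) and Ankrd1 for Wnt5a siRNA without stretch (−0.36, 0.0352) and in the interaction (−0.56, 0.0294). Of the lists described it lost NF-kB targets for Wnt5a siRNA without stretch (0.0549) and called smooth muscle markers for Wnt5a siRNA under stretch (0.0311) and in the interaction (0.0384). As a hint from the data, 11 of 12 libraries correlated best with their own number.

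The depth is unknown, so how much of the spread of low genes is counting error cannot be given. In simulated data of this size 76% to 83% of changes of 1.5-fold were called in comparisons of groups and 36% in the interaction, which limits what the absence of an interaction call says.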

Other observations

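The genes and groups described here were chosen after the data were seen, and so were all tests in this part. The groups were not tested for enrichment. Of 15 genes of the circadian clock 5 rose and 2 fell with stretch and control siRNA, no larger a share than the 5711 of all 10518 genes. With control siRNA the activator Arntl (Bmal1) rose by 1.11 ± 0.09 on the log2 scale (limma adjusted p = 3.0e-06) and the repressors Ciart and Nr1d1 by 1.08 and 0.43 (adjusted p = 4.7e-06 and 7.9e-04). The output gene Dbp fell by 0.92 (22.3 ± 1.79 to 11.4 ± 2.48 FPKM, 2.3e-04) and Per3 by 0.94 (1.2e-04). With Wnt5a siRNA the change of Arntl was 0.60 (0.0012), that of Per3 −0.66 (0.0069), and Dbp at −0.11 (0.655), Ciart at −0.25 (0.104) and Nr1d1 at −0.18 (0.165) did not pass. The interaction was called for Arntl (−0.51, 0.0141), Ciart (−1.33, 4.6e-04), Nr1d1 (−0.61, 0.0045) and Dbp (0.81, 0.0167) and not for Per3 (0.318). With stretch and Wnt5a siRNA, lower calls came from TPM scaling for Ciart (0.0338) and Nr1d1 (0.0172, range 0.0172 to 0.438 over the alternatives), and from a fit without a trend for Ciart (0.0397, range 0.0338 to 0.252). With Wnt5a siRNA under stretch 1 of the 15 rose and 7 fell. Without stretched control 3 the counts were 5 and 3 with stretch and 3 and 7 with the siRNA. The time of day of collection is not given in the sources used here.

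All 12 genes of amino acid synthesis, transport and the ATF4 response examined, such as Atf4 and Trib3, rose with Wnt5a siRNA without stretch, where 1536 of 10518 genes rose. Slc7a5, an amino acid transporter, rose by 1.17 (adjusted p = 9.3e-04) and Phgdh, a serine synthesis enzyme, by 0.91 (0.0196). Phgdh did not pass without unstretched control 1 (0.066) or 3 (0.0527) or unstretched Wnt5a siRNA 1 (0.0536) or 2 (0.0543, range 1.1e-04 to 0.066). Under stretch 7 rose and 1 fell with the siRNA, and 8 and 1 without stretched control 3. Of 13 receptors and transcription factors of cardiomyocytes 1 rose and 7 fell with stretch and control siRNA, where 2822 of all genes fell, or 2 and 7 without stretched control 3. The adrenergic receptors Adra1b and Adrb1 were at −1.79 (4.6e-06) and −1.35 (1.0e-06) and Tbx5 at −1.36 (1.3e-06).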
